A study of Mus musculus with 10 samples.

How the data were processed

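RNA from lung tumours of 10 mouse samples was measured on Agilent two-colour expression arrays, 5 from cisplatin-treated and 5 from PBS-treated mice. Per the labels, tumour RNA carried Cy5 (red) and a commercial pooled mouse reference RNA carried Cy3 (green) on every array, and no array had the dyes swapped. A positive log2 ratio therefore stands for more signal in the tumour than in the reference, and a dye effect of a gene is the same in both groups. The samples were assigned to their groups by their titles. The labels call the samples biological replicates but do not say that each came from a separate animal, and tumours were combined before extraction. The p-values therefore measure only the spread between these samples.

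Per the file headers, the authors scanned the arrays and extracted spot intensity with Agilent Feature Extraction 10.7.3.1, and the submitters' processing notes name Feature Extraction 10.7 and limma. The deposited scanner files give, per spot, the median intensity of each channel, the median intensity of the local background, a processed intensity and a log10 ratio. Per the file headers the processed intensity was background-corrected with spatial detrending and dye-normalised by lowess. The deposited log10 ratio lay within 0.01 of the log10 of processed red over processed green for 88.8% of spots, and the other spots were not examined. The authors also deposited a table of log2 values of the same arrays. Its scale, centring and direction are not stated, and were found by setting each column against the scanner values of that array. Each column correlated with the normalised log2(red/green) values described here at r = 1.00 over 41174 probes, with slopes of 0.991 to 1.00 and medians of 0.01 to 0.02, so it holds centred log2 ratios of tumour over reference. How the authors computed these values is not given in the sources used here.

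The analysis started from the scanner files, with R 4.3.3, limma 3.58.1, data.table version 1.17.8 and statmod 1.5.0. The plan made before the data were examined named mean spot signals, which are not among the columns used here, so median spot signals took their place. Background was corrected with normexp (offset 50), and ratios were normalised by loess within each array, with control spots at weight 0 and no scaling between arrays. Control spots were then removed, spots with a non-uniformity or population outlier mark from Feature Extraction were set to missing, and spots of one probe were averaged.

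One step departs from that plan, and it was chosen after the number of genes called without it had been seen. The plan fitted normexp on every spot. On cisplatin replicate 3, 8 spots had red local backgrounds of 951 to 755432, where the array medians were 79.5 to 89. With these spots in the fit, the red normexp mean of that array was -2783, against -16.4 to -11.7 on the other arrays, and its median correlation with them was 0.684. Spots whose local background Feature Extraction marks as non-uniform, 69 over the 10 arrays and 0 to 21 per array, were therefore kept out of normexp and set to missing. The red normexp mean of that array was then -12.5. Its green normexp mean moved from -29.6 to 3.74, and that of PBS 2 from -33.9 to 0.87. The median correlation of PBS 2 with the other arrays was 0.957 with every spot fitted and 0.956 under this step. The deposited log2 values, which were compared only afterwards, correlated with cisplatin replicate 3 at 1.00 under this step and at 0.691 with every spot fitted. With every spot fitted as planned, limma called 0 genes (1497 at an unadjusted p below 0.05) and camera called 15 gene lists, of which 8 were also called here in the same direction and 1, the Fanconi list, in the other. The deposited log2 values, whose use was planned and whose handling of such spots is not known, gave 68 called genes, all 68 among the 81 called here.

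Probes were named through the accession in the scanner files, matched without version to a table of mouse genes (GRCm38.p6) used for names only. Of 41174 probes, 22951 matched 1 gene symbol, 0 matched several and 18223 matched none. The file headers name another genome build, so no coordinates are given. A probe was kept when it was well above background in red on at least 5 of the 10 arrays, whatever their group. The probe of highest mean intensity stood for a gene, and probes without a symbol stayed as features of their own, which left 23803 features, 13898 of them named. No named gene was below background on all arrays of a group.

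Genes were tested with limma (lmFit and eBayes, group only), two-sided, with Benjamini-Hochberg adjustment over all features. A gene counts as called at an adjusted p below 0.05. Of 61 gene lists fixed before the data were examined (responses to cisplatin, proliferation, metabolism, tumour state, cell types and signs of handling), 58 had the 5 or more measured genes needed for a test. Lists were tested with camera at a preset correlation of 0.01, adjusted over the 58 lists. Beside it stood camera with a correlation estimated per list, and fry. Fry's directional p tests whether the genes of a list move, on balance, one way, and its mixed p whether they change in either direction. Neither compares the list with other genes. The inflammatory, senescence, RAS output, immediate early and glucocorticoid lists share members, 10 of the 24 NF-kB genes and 7 of the 24 senescence genes being in other lists too.

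Genes to be named were set by a rule fixed before the data were examined. In each direction it takes the 15 genes of largest log2 change among called genes whose groups do not overlap, and, where fewer exist, adds the genes of smallest p until 10 are named, called or not. It adds the 4 members of smallest p from each list described, and Kras and Trp53. Features known only by an accession are counted and not named, and sex-linked genes are given only as a list.

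The arrays lay on 6 slides, of which 4 held 1 array of each group. Position 1 on the slide held only PBS arrays and position 3 only cisplatin arrays, while position 2 held 3 PBS and 2 cisplatin arrays. Slide (as a fixed and as a random block) and position were fitted as alternatives. In all, 35 alternative settings were run, 32 of them planned as alternatives and 3 added after seeing the data, among them the planned fit on every spot. They cover background correction, normalisation, filters, the probe rule, covariates, the variance model, thresholds, the list test and each array left out in turn. The planned settings that start from scanner signals kept the step on spots of non-uniform background.

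The gene test and the list test were tested on simulated data made from the comparison's own 23803 features. With 50 genes changed at each size, 33 were called at 1.5-fold, 48 at 2-fold, 50 at 3-fold and 50 at 4-fold, with 11 false calls and 0 of wrong sign. All 4 shifted lists were found, and 0 of 36 unshifted lists were called. The simulated noise was independent between genes, and the lists were drawn at random. The list result therefore does not cover lists of correlated genes, such as the mitotic list (estimated correlation 0.777). Between 57.7% and 77.5% of probes were well above background in red per array, with median red intensities of 168.5 to 248 and median green intensities of 104 to 138. No 2 arrays held identical values. The closest pair, cisplatin replicates 1 and 2, correlated at 0.980 over features. The number of arrays limits the precision of every value.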

Results

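The data compare lung tumours of mice that had received cisplatin, a platinum drug that crosslinks DNA, with tumours of mice that had received the vehicle PBS. The mice carried an activatable Kras G12D allele and floxed p53 alleles, and inhaled adenoviral Cre started the tumours. Cisplatin was given weekly at 7 mg/kg, by the series' description until the tumours were resistant, and dissected tumours were combined for RNA. Each of the 5 cisplatin and 5 PBS samples was hybridised to 1 array against the same pooled mouse reference. The question was which genes differ between tumours of cisplatin-treated and PBS-treated mice. No treated tumours that stayed sensitive were among the samples, so resistance cannot be told apart from repeated exposure to the drug. Values are log2 ratios of tumour over reference, given as mean ± SD with n = 5 per group, and changes are cisplatin minus PBS on the log2 scale.

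Among the called genes with a symbol that were higher after cisplatin, the interferon-inducible genes Rsad2 and Gbp2 had the largest changes. Rsad2, an antiviral enzyme induced by interferon, rose from -2.05 ± 0.59 to -0.48 ± 0.32, a 2.96-fold difference (SE 0.26 log2, adjusted p = 0.0373). Its 3 probes did not move alike, with changes of -0.01 to 1.57. Gbp2, an interferon-inducible guanylate-binding protein, rose from -0.33 ± 0.24 to 1.20 ± 0.61 (2.88-fold, adjusted p = 0.0373). The transcription factor Klf4 rose by 1.35 (SE 0.21, adjusted p = 0.0323) and the nuclear receptor Nr4a2 by 1.23 (SE 0.18, adjusted p = 0.0268). Dio3, which inactivates thyroid hormone, rose by 1.45, Trim69 by 1.44 and the cytokine Il19 by 1.17. Smaller rises were those of Ier5, Zfp296 (1.01 ± 0.12 SE, adjusted p = 0.0211), Cdk5r1 (0.999), Necab2 (0.99), Zfp131 (0.85), Adamts15, H2ap (0.83) and Tiparp (0.81). These 15 genes rose between 1.76-fold and 2.96-fold, and for each of them all 5 cisplatin arrays lay above all 5 PBS arrays, as the naming rule required.

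Among the genes that were lower, Bbc3, which encodes the p53-inducible killer protein PUMA, fell from 1.16 ± 0.29 to 0.25 ± 0.21 (fell by 0.91 on the log2 scale, SE 0.15, adjusted p = 0.0327). Il34, a ligand of the macrophage receptor CSF1R, fell by 0.66 (SE 0.09, adjusted p = 0.0250). The lysophosphatidic acid receptor Lpar6 fell by 0.68, the zinc finger gene Zfp120 by 0.69, the poly(A) polymerase Papolg by 0.54, Clic3 by 0.38 and Dhps, an enzyme of hypusine synthesis, by 0.35. Rcan2 was called at -0.89 although its groups overlapped by 1 array of each, and its other probe gave -0.18. Pnrc2 (-0.41, adjusted p = 0.0533) and Zfp160 (-0.56, adjusted p = 0.0568) were not called. Of the genes altered in the model, Kras differed by -0.23 (SE 0.15, adjusted p = 0.574) and Trp53 by 0.06 (SE 0.08, adjusted p = 0.820). The 2 Trp53 probes gave -0.11 and 0.06.

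**Figure D1:**
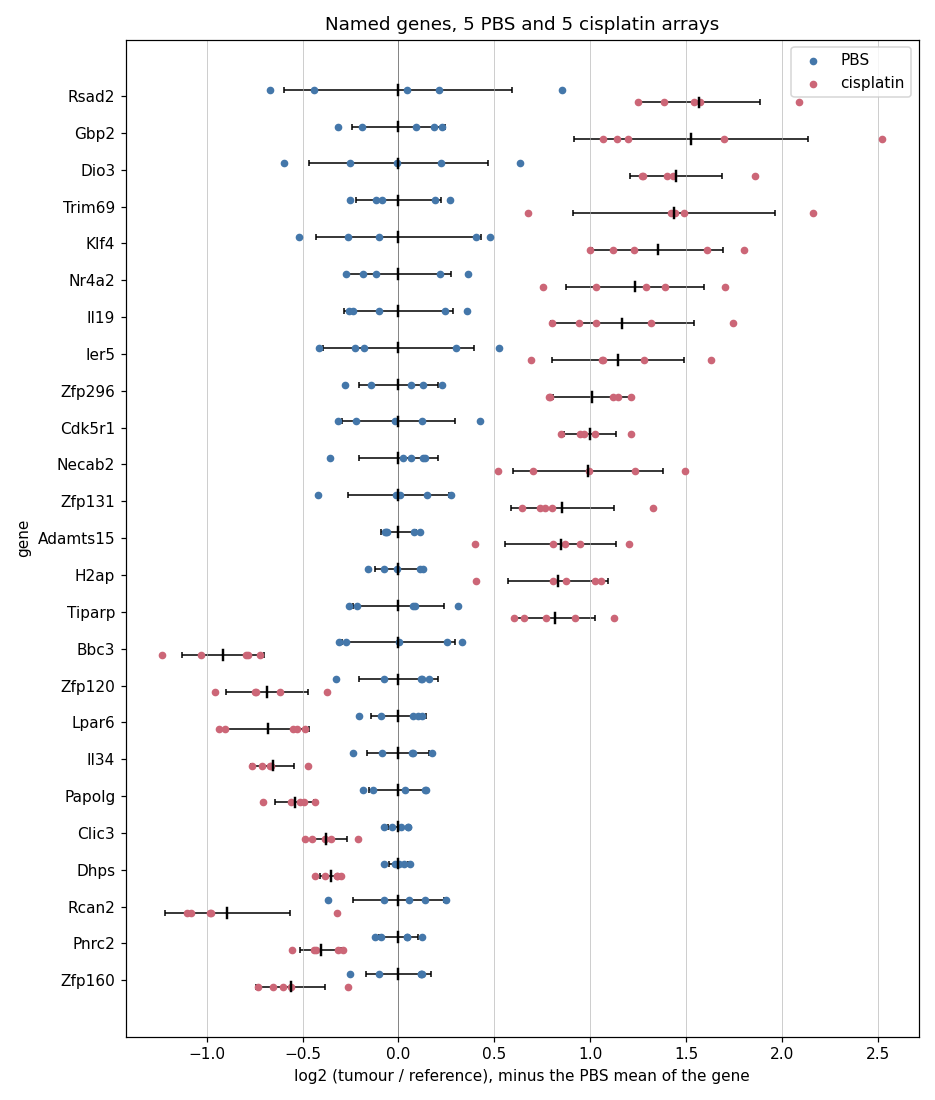
The 15 named genes that were higher and 10 that were lower after cisplatin, 1 row per gene, with log2 (tumour / reference) minus the gene's PBS mean on the horizontal axis; points are arrays (5 PBS in blue, 5 cisplatin in red), black ticks the group means and bars 1 SD. The groups do not overlap for Rsad2 at 1.57 or Bbc3 at -0.91, and they overlap for Rcan2.

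Over all 23803 features, limma called 81, of which 69 were higher and 12 lower after cisplatin. Other planned processing moved that number, to 274 with median centring (97.1% of them higher, against 85.2% of the 81), 45 with scale between arrays, 33 from processed signals (93.9% higher), 49 with probes well above background on all arrays, 2 in the red channel alone and 0 with same-numbered samples as blocks. Of the 81, 46 had a gene symbol, 38 of them higher and 8 lower. The groups did not overlap for 80 of the 81, and for 776 of all features (3.26%, where chance gives 0.794%). At an unadjusted p below 0.05 there were 2935 features, against 1190 expected by chance. The adjusted p of the called genes lay between 0.0211 and 0.0488, close to the threshold, and the calls depended on single arrays. Leaving out PBS 1, PBS 3 or cisplatin 2 left 0 called genes in limma (2769, 2621 and 2382 at an unadjusted p below 0.05). There were 8 without PBS 2, 8 without cisplatin 5, 11 without cisplatin 1, 22 without PBS 4, 81 without PBS 5, 92 without cisplatin 3 and 250 without cisplatin 4. Each of the 23 called genes named here lost its call in 3 (Zfp296) to 10 (Clic3) of the 10 omissions. With every spot in the background fit, as planned before the data were examined, limma called 0 genes (1497 at an unadjusted p below 0.05).

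With slide as a random block (correlation 0.007) all 81 were among the 88 called. Few calls stood when slide as a fixed block or position was fitted beside the treatment. The fixed block takes the treatment difference only from the 4 slides that held both groups. On slides 1 and 2 PBS lay at position 1 and cisplatin at position 2, and on slides 3 and 4 they lay at positions 2 and 3. The differences on the slides and the fixed block therefore cannot tell treatment apart from position. The position fit takes it only from position 2, with 3 PBS and 2 cisplatin arrays, so its change of a gene is the difference there. Calls may be lost through fewer arrays alone. With slide as a fixed block 29 features were called, 11 of them among the 81, and the changes were 1.58 for Rsad2, 1.43 for Gbp2, 1.34 for Klf4 and -0.90 for Bbc3. Of the 25 genes, only Dio3, Klf4 and Cdk5r1 stayed called in that fit. At position 2, the only one to hold both groups, the differences were 1.62 for Rsad2, 1.92 for Gbp2, 0.92 for Klf4 and -0.82 for Bbc3. With position as a fixed effect 4 features were called, 1 of them among the 81. None of the 25 genes stayed called in that fit (0 of 25).

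The groups of genes that shifted upwards were led by inflammatory NF-kB targets. Of 24 measured genes 23 were higher, by 0.64 on average (camera adjusted p = 1.33e-09; adjusted p = 0.581 with an estimated correlation). None of them was called among all genes, and 9 were called adjusted over the list alone. The cytokine Il6 differed by 2.14 (SE 0.52, adjusted p = 0.111), the neutrophil chemokine Cxcl2 by 2.19 (SE 0.54, adjusted p = 0.113), Ccl2 by 0.56 and Ccl5 by 0.36, and none of these 4 passed the test. The mean difference of the list was 1.15, 0.76, 0.62 and 0.02 on the 4 slides, 0.64 with slide as a block and 0.38 at position 2. Interferon-stimulated genes shifted by 0.40 on average, with 28 of 34 higher (camera adjusted p = 2.02e-06; adjusted p = 0.581 with an estimated correlation). Rsad2 and Gbp2 were called among all genes and 6 members adjusted over the list alone, and the immunity-related GTPases Iigp1 (1.54) and Igtp (1.25) were not called among all genes. This list differed by 0.21 to 0.78 on the slides, by 0.40 with slide as a block and by 0.58 at position 2. MHC class I genes shifted by 0.18, with 11 of 13 higher and 0 called (camera adjusted p = 0.0403; adjusted p = 0.712 with an estimated correlation). The immunoproteasome subunit Psmb10 stood at 0.28, H2-T23 at 0.36, Tap2 at 0.43 and Tapbp at 0.17. The difference of this list was -0.13 to 0.57 on the slides, and without cisplatin 2 the mean change was 0.11.

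The lists of immediate early genes and of glucocorticoid targets moved in the same direction, and what induced these genes was not tested. Immediate early genes, which respond within minutes to dissection or stress, shifted by 0.34, with 15 of 20 higher (camera adjusted p = 0.00475; adjusted p = 0.614 with an estimated correlation). Klf4 was called among all genes and 5 members adjusted over the list alone, 4 of them higher and 1 lower. Myc (1.46) and Klf6 (0.61) were higher without passing the test over all genes, and Btg2 stood at -0.51, against the list. Glucocorticoid targets shifted by 0.41, with 11 of 13 higher and 5 called adjusted over the list alone (camera adjusted p = 0.00420; adjusted p = 0.581 with an estimated correlation). The kinase Sgk1 differed by 1.37, Errfi1 by 0.61, the cell cycle inhibitor Cdkn1a by 0.79 and the metallothionein Mt2 by 0.61, with 0 called among all genes. At position 2 the difference of this list was 0.12, and with position as a fixed effect its call was lost (adjusted p = 0.535). Outputs of RAS-ERK signalling shifted by 0.39, with 12 of 20 higher and 5 called adjusted over the list alone (camera adjusted p = 0.0137; adjusted p = 0.581 with an estimated correlation). Fosl1 (1.48), the EGFR ligand Hbegf (1.08) and Phlda1 (0.92) led it with Myc, and at position 2 the difference was 0.25 (adjusted p = 0.0607 with position as a fixed effect). The senescence and secretory list, which holds Il6, Cxcl2, Ccl2 and Cdkn1a, shifted by 0.34, with 13 of 24 higher and 4 called adjusted over the list alone (camera adjusted p = 0.0429; adjusted p = 0.581 with an estimated correlation). On the 4 slides immediate early genes differed by 0.03 to 0.72 (0.25 at position 2) and glucocorticoid targets by 0.19 to 0.60.

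Detoxification genes and keratins of the basal and squamous list were also shifted. Glutathione and NRF2 target genes shifted by 0.23, with 29 of 34 higher and 0 called (camera adjusted p = 1.07e-04; adjusted p = 0.581 with an estimated correlation). Sulfiredoxin Srxn1 differed by 1.12, Osgin1 by 0.74, the epoxide hydrolase Ephx1 by 0.31 and Taldo1 by 0.30, and none passed the test. Cisplatin 3 lay apart in this list at 0.56 above the mean of the 10 arrays, where the other cisplatin arrays lay at -0.05 to 0.10. Without cisplatin 3 the mean change was 0.12, and with position as a fixed effect it was 0.12 and not called (adjusted p = 0.0532). Markers of basal and squamous cells shifted by 0.32, with 9 of 11 higher and 4 called adjusted over the list alone (camera adjusted p = 0.00131; adjusted p = 0.581 with an estimated correlation). These 4 were the keratins Krt15 (0.64), Krt6a (0.64), Krt13 (0.47) and Krt6b (0.24), and cisplatin 3 was again the highest array at 0.30. The other members, Trp63, Krt5 and Krt14 among them, were not called. Genes of cholesterol and fatty acid synthesis shifted by 0.14, with 21 of 28 higher and 0 called (camera adjusted p = 0.0219; adjusted p = 0.784 with an estimated correlation). Acly (0.29), Pcsk9 (0.30), Sc5d (0.21) and Scd2 (0.37) had the smallest p. That list differed by -0.35 to 0.47 on the slides and by 0.04 with slide as a block (adjusted p = 0.623). Its mean change was 0.09 without PBS 2, PBS 5 or cisplatin 3.

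Mitotic genes formed the clearest group on the lower side. All 34 measured genes of G2/M and mitosis were lower, by -0.44 on average (camera adjusted p = 1.99e-10; adjusted p = 0.614 with an estimated correlation). Of these, 12 were lower at an unadjusted p below 0.05 and 0 were called, over all genes or adjusted over the list alone. The anaphase activator Cdc20 differed by -0.81 (SE 0.29, adjusted p = 0.274), Nuf2 by -0.60, Nek2 by -0.46 and Cdk1 by -0.41 (-0.17 on its other probe). The array means of the list overlapped between the groups, and cisplatin 3, whose correlation with the other arrays was the lowest (median 0.936, the next lowest 0.956), lay below all other arrays at -0.82 about the mean of the 10 arrays. PBS 2 lay above all other arrays at 0.72, where the other PBS arrays lay at -0.18 to 0.39. Without cisplatin 3 the mean change was -0.29, and without PBS 2 it was -0.31. On the 4 slides it was -0.26, -0.46, 0.06 and -0.54, with slide as a block -0.30, and at position 2 it was -0.13, where the fit with position as a fixed effect did not call it (adjusted p = 0.133). With every spot in the background fit, as planned, it was 0.03.

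The G1/S, Fanconi, mismatch repair and checkpoint lists were also lower under the background step used here. Only the mismatch repair mean stayed negative under the planned one, without being called (camera adjusted p = 0.349). G1/S and DNA replication genes shifted by -0.15, with 25 of 33 lower and 3 called adjusted over the list alone, 2 of them lower and 1 higher (camera adjusted p = 0.00301; adjusted p = 0.784 with an estimated correlation). Mcm3 (-0.53, and -0.20 on its other probe), Rfc4 (-0.35) and Rpa2 (-0.27) were lower without passing the test over all genes, and the replication initiation factor Mcm10 stood at 0.71, against the list. Fanconi anaemia and homologous recombination genes, which repair crosslinks, shifted by -0.12 with 20 of 27 lower (camera adjusted p = 0.0179; adjusted p = 0.784 with an estimated correlation). Exo1 (-0.49), Eme1 (-0.28) and Rad51ap1 (-0.30) were lower, and the helicase Brip1, the only member called adjusted over the list alone, stood at 0.60 on 1 probe and -0.03 on the other. Mismatch repair genes shifted by -0.23 with 6 of 6 lower (camera adjusted p = 0.0219; adjusted p = 0.581 with an estimated correlation), among them Msh6 (-0.41), Pms1 (-0.35), Pms2 (-0.28) and Msh2 (-0.14). DNA damage checkpoint genes shifted by -0.12 with 12 of 16 lower (camera adjusted p = 0.0228; adjusted p = 0.581 with an estimated correlation), among them Tipin (-0.36), Rad1 (-0.28), Topbp1 (-0.19) and Wee1 (-0.18). Cisplatin 3 was the lowest array in each of these lists, at -0.41 (G1/S), -0.31 (Fanconi), -0.42 (mismatch repair) and -0.14 (checkpoint) about the mean of the 10 arrays. Without it the mean changes were -0.07 for G1/S, -0.05 for Fanconi and -0.16 for mismatch repair. With slide as a block the changes were -0.07, -0.06, -0.16 and -0.10 in the same order, and the call was lost for G1/S (adjusted p = 0.0694), Fanconi (adjusted p = 0.101) and mismatch repair (adjusted p = 0.133) and kept for the checkpoint list (adjusted p = 0.0468). At position 2 they were 0.01, 0.005, -0.09 and -0.06. With every spot in the background fit, as planned, they were 0.06, 0.17, -0.12 and 0.03, and the Fanconi list was called higher (adjusted p = 0.0290) and the other 3 were not called. PBS 2 was the highest array of the Fanconi (0.21), mismatch repair (0.16) and checkpoint (0.22) lists. Without PBS 2 the mean changes of these lists were -0.08, -0.22 and -0.08.

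**Figure D2:**
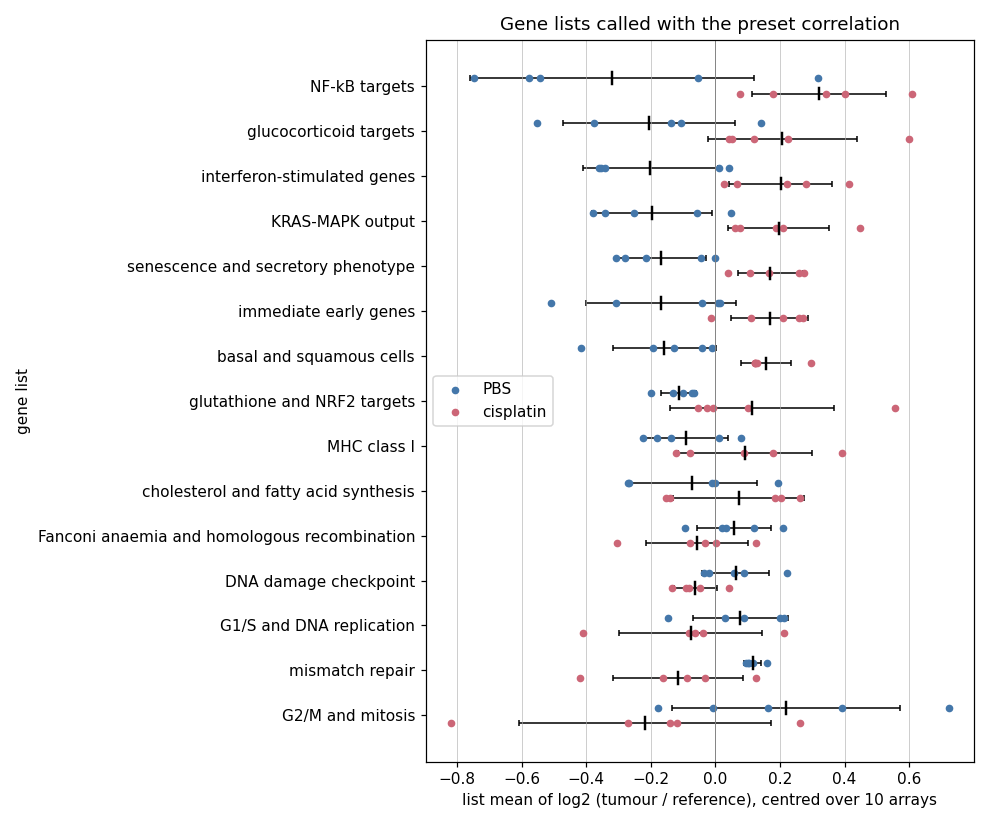
The 15 gene lists called by camera with the preset correlation, 1 row per list, with the list's mean log2 (tumour / reference) centred on the 10 arrays on the horizontal axis; points are arrays (5 PBS in blue, 5 cisplatin in red), black ticks the group means and bars 1 SD. The groups do not overlap in 4 of the 15 lists, and cisplatin 3 is the lowest point of G2/M and mitosis at -0.82.

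Several groups tied to cisplatin were not called by camera, although fry's mixed test, which takes changes in either direction, called p53 targets (adjusted p = 0.0144) and apoptosis regulators (adjusted p = 0.00557). Targets of p53, the gene that Cre deletes in this model, differed by 0.04 over 32 genes (0.005 without cisplatin 3; camera adjusted p = 0.699), with Bbc3 called lower and Cdkn1a (0.79), Btg2 (-0.51) and Cd80 (-0.18) not called. Regulators of apoptosis differed by -0.08 over 29 genes (-0.04 without cisplatin 3; camera adjusted p = 0.880). Next to Bbc3, Bmf stood at -0.96 on the brightest of 3 probes and at 0.02 on another, Casp2 at -0.57 and Cycs at 0.21. Nucleotide excision repair genes differed by -0.02 over 21 genes (camera adjusted p = 0.743), with Rad23b at 0.23, Ercc8 at -0.22 (0.03 on its other probe) and Lig1 at -0.25. Transporters linked to platinum uptake and export differed by 0.002 over 16 genes, the camera test pointing the other way from the mean (adjusted p = 0.918), with Slc47a1 at -0.28, Abcc1 at 0.23, Lrrc8d at -0.11 and Atp7a at 0.27. Epithelial genes differed by 0.10 (0.06 without PBS 3 and -0.24 with every spot in the background fit; camera adjusted p = 0.415), with Krt8 at 0.58, Krt18 at 0.41, Pkp3 at 0.16 and Elf3 at -0.21. Of 22 cell type lists tested, only the basal and squamous list was called. Over the 43 lists that were not called the mean changes were -0.23 to 0.19.

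Of the 58 lists tested, camera with the preset correlation called 15, of which 10 were higher and 5 lower. With an estimated correlation 0 were called, and the smallest adjusted p was 0.581. Fry called 1 list by direction, cytotoxic and NK cells (adjusted p = 0.0477), which camera did not call, and 15 lists by its mixed test. Of the 15 lists, 11 were called with slide as a block, the G1/S, Fanconi, mismatch repair and cholesterol lists being lost. With position as a fixed effect 6 were called, namely NF-kB, interferon, MHC class I, cholesterol, immediate early and basal and squamous. On all 4 slides 10 of the 15 differed in the same direction, which is given in advance for the 4 whose groups do not overlap. On each of these slides the cisplatin array lay at a later position than the PBS array. With every spot in the background fit, as planned, 8 of the 15 were called in the same direction, the Fanconi list was called in the other, and the basal and squamous, cholesterol, mitosis, G1/S, mismatch repair and checkpoint lists were not called. In 7 lists (NF-kB, interferon, glutathione and NRF2, basal and squamous, glucocorticoid, RAS-ERK output and mitosis) the call stood in each of the 10 omissions. The other 8 lost it in at least 1. Those were the immediate early list without PBS 2 (adjusted p = 0.0917), mismatch repair (0.188) and G1/S (0.0832) without cisplatin 3, and the checkpoint list without PBS 2 or cisplatin 4 (0.0513 to 0.109). The Fanconi list lost it without PBS 2, PBS 4 or cisplatin 3 (0.0652 to 0.201). The senescence list lost it without PBS 1, 2 or 3 or cisplatin 2, 4 or 5 (0.0521 to 0.141), and MHC class I without PBS 1, 2 or 5 or cisplatin 1, 2 or 5 (0.0559 to 0.184). The cholesterol list lost it without PBS 2 or 5 or cisplatin 1, 2 or 3 (0.0783 to 0.173). Over the alternatives the adjusted p lay between 1.41e-14 and 0.581 for NF-kB targets and between 1.40e-15 and 0.905 for mitosis.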

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

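The splits of the arrays were planned, and the tests on cisplatin 3, on the mitotic genes and on the NF-kB targets were chosen after those results were seen.

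The groups of 5 arrays were searched for a single array far from the other 4. Of 234 groups of values checked, 18 held one, where chance alone gives about 11.7 (1 in 20), and 7 of the 18 were cisplatin 3. Among genes led by one array, Osgin1 was 4.93 in cisplatin 3 (the other 4 arrays 3.54 to 3.88) and 2.78 in PBS 2 (3.22 to 3.34). Igtp was 2.52 in cisplatin 2 (1.09 to 1.17), Krt6a 1.77 in cisplatin 3 (0.94 to 1.18) and Klf6 2.26 in PBS 2 (2.80 to 3.01). Tap2 was -1.33 in PBS 1 (-0.22 to 0.07), Tapbp 0.76 in PBS 4 (0.55 to 0.59) and Necab2 0.45 in PBS 2 (0.83 to 0.94). Tipin was -1.57 in PBS 2 (-2.20 to -2.07) and -2.86 in cisplatin 3 (-2.36 to -2.16). In cisplatin 5, Dio3 was 3.43 (2.84 to 3.00), Zfp131 1.90 (1.22 to 1.38), Rcan2 1.57 (0.79 to 0.92) and Scd2 -0.54 (0.16 to 0.33). In cisplatin 3, Sc5d was 0.84 (0.28 to 0.39) and Rad23b 0.082 (-0.28 to -0.21). In that array the mean of glutathione and NRF2 targets was 0.56 (-0.05 to 0.10) and that of basal and squamous markers 0.30 (0.12 to 0.13).

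Cisplatin 3 correlated less with the other arrays than they did with each other. Spots with an extreme local background are not the whole cause, since its median correlation was still 0.936 with them left out, below the 0.956 of the next lowest array. Weak hybridisation does not account for it, since 70.6% of its probes were well above background in red, where the dimmest other array had 57.7%. It was 1 array alone on its slide, so slide and sample cannot be told apart. A difference in the tumours themselves may also explain it, and no biological explanation was tested.

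The 34 mitotic genes were lower by -0.44 on average after cisplatin. Whether they were lower through cisplatin 3 alone cannot be told, since the mean without it was -0.286 with an SE of 0.205 between arrays. The list mean was not lower in every treated sample. Centred on all arrays, cisplatin 1 lay at 0.261, above PBS 1 (-0.009), PBS 3 (-0.179) and PBS 5 (0.163). It lay below PBS 2 (0.722) and PBS 4 (0.393). PBS 2 was the highest array, and without PBS 2 the mean change was -0.31. The epithelial list does not separate tumour from normal epithelium, so it cannot speak to the share of tumour cells alone. A smaller share of epithelium as a whole is argued against by its mean of 0.095 (SE 0.06 between arrays), above the -0.218 that the test required. That holds under the processing used here, and the epithelial mean was -0.081 with scale between arrays and -0.24 with every spot in the background fit, where the mitotic genes were not lower (0.033). Slower division of the treated tumours may be the cause, as may chance, since the estimated correlation of 0.777 between these genes leaves the shift at an adjusted p of 0.614.

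NF-kB targets were higher by 0.64 on average. More immune cells in the tissue are argued against, since the mean changes of 8 immune cell lists had a median of 0.021 (-0.127 to 0.086), under the 0.321 that the test required. Handling or stress before extraction remains a candidate explanation, as the immediate early list was called higher too (adjusted p = 0.00475, but 0.614 with an estimated correlation and 0.0917 without PBS 2), and a response of the tumours to cisplatin could give the same values. The list of heat shock and protein folding genes was not called (mean 0.025 over 12 genes, camera adjusted p = 0.883). With position as a fixed effect it was called lower (-0.304, camera adjusted p = 0.00487). Position on the slide cannot be told apart from the treatment, since the difference at position 2 was 0.382 with an SE of 0.273 over 5 arrays.

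Chance was tested by splitting the 10 arrays into other groups of 5. The real split called 81 genes. Of 100 splits (of 126 possible), 1 gave as many, the real one, with 7 the highest of the others. The background step was chosen after the real split had called 0 genes under the planned fit, and not anew for each split. The comparison therefore favours the real split and cannot exclude chance for that number. Nor can chance be excluded for the number of lists. As many as the real 15 were called by 12 of 100 splits, the real one among them, with 17 the highest of the others and 9 their median.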

How the results depend on the processing

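The step that keeps spots out of the background fit was chosen after seeing the data, so the planned fit on every spot stands here as an added alternative. The split by sex-linked genes and the fit on every spot without cisplatin 3 were also chosen after seeing the data, and the rest were planned before. The cause of a moved value was not tested, except where fewer arrays, fewer genes or another threshold make it. The 81 called genes (69 genes higher in cisplatin, 12 genes lower in cisplatin) and 15 lists stayed within 1.5 times under Aquantile scaling (81), no background correction (74), no filter (75), the mean of probes (90), slide as a random block (88), trend and robust variances (105) and array weights (111). Fewer were called from processed signals (33, as 31 and 2) and with scale between arrays (45, as 38 and 7, with 10 lists). Fewer were also called with probes well above background on all arrays (49, as 43 and 6) and in the red channel alone (2, as 1 and 1). Slide as a fixed block called 29 (27 and 2), position 4 (4 and 0, with 8 lists), and the estimated correlation 0 lists. More were called with median centring (274, of which 266 or 97.1% were higher, against 85.2% of the 81) and at an adjusted p below 0.1 (311, as 261 and 50). Only the lower genes moved with normexp offset 0 (5), the deposited log2 values (7), every probe on its own (7) and a 1.5-fold minimum (6). Leaving out 1 array at a time called 0 to 250 genes, 0 to 230 higher and 0 to 20 lower, and 9 to 16 lists. The replicate block called 0 genes (0 higher, 0 lower; 2612 at an unadjusted p below 0.05) and 15 lists. Same-numbered samples did not deviate together (correlations -0.36 to 0.104). Arrays that shared a slide did not either (-0.246 to 0.078), so this measure cannot tell whether the numbers pair samples.

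Every spot in the normexp fit, as first planned, called 0 genes (0 higher, 0 lower) in limma and 15 lists, 9 of them among the 15 given here and 8 in the same direction. Leaving cisplatin 3 out of that setting gave 94 higher and 13 lower genes, 63 of them shared. That setting turned the sign of Exo1 (0.093), Eme1 (0.03), Rad51ap1 (0.26), Rad1 (0.04), Topbp1 (0.11), Pms2 (0.025), Nuf2 (0.039), Slc47a1 (0.20) and Pkp3 (-0.11), and of the Fanconi (0.17), checkpoint (0.031), G2/M (0.033), G1/S (0.06) and epithelial (-0.24) lists, of which the Fanconi list was called higher (adjusted p = 0.0290). Other turned signs were mostly those of small values. Among them were the epithelial list with scale between arrays (-0.081), Trp53 (-0.19) and the excision repair test (-0.007) in red alone, Trp53 with the mean of probes (-0.024), and with position Lig1 (0.089), Abcc1 (-0.036) and the lists of excision repair (0.01), Fanconi (0.005), G1/S (0.014) and p53 targets (-0.009). The excision repair mean also turned with median centring (0.033). The apoptosis list's test turned with slide as a block (mean -0.039) and position (-0.03), and it was -0.096 to -0.043 over the omissions. The platinum transport list's test turned with no filter (0.009), all arrays above background (0.011) and ranks (0.002), and was -0.018 to 0.016 over the omissions. Its mean of 0.002 was below 0 in red alone (-0.036), normexp offset 0 (-0.015), every spot fitted (-0.014), processed signals (-0.011), position (-0.008), scale (-0.001) and the mean of probes (-0.001). Of the other values of single genes over all settings but the omissions, 1915 kept direction and side of the threshold, 192 lost the call and 33 gained it, and of lists, by the direction of the list test, 363 kept both and 64 lost the call. In the omissions 769 gene values kept both, 166 lost the call and 5 gained it. The share of probes well above background in red, 57.7% on PBS 3, limits what can be said of dim genes.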

Other observations

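The fixed effect of the split by sex-linked genes was chosen after the result was seen, and the list tests given here were planned.

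Markers of lymphocytes, alveolar cells and club cells were not called by camera. Cytotoxic and NK genes were higher in 7 of 9 members with a mean of 0.09 and 2 called adjusted over the list alone, the only list that fry called by direction (adjusted p = 0.0477; camera adjusted p = 0.103). T cell genes (-0.03 over 18 genes), B and plasma cell genes (0.01 over 16) and MHC class II genes (0.02 over 9) were not called. The MHC class II mean rested on cisplatin 3, which lay at -0.82 about the mean of the 10 arrays, and was 0.22 without it, 0.23 with slide as a block and 0.32 at position 2. Markers of alveolar type 2 cells, the surfactant-producing cells of the lung, were lower in 17 of 20 genes with a mean of -0.09 (camera adjusted p = 0.0615), and markers of alveolar type 1 cells were higher in 9 of 12 with a mean of 0.17 (camera adjusted p = 0.139). Without cisplatin 3 these means were -0.04 and 0.10. Club cell markers, of secretory airway cells, were lower in 8 of 11 genes with a mean of -0.23 and 1 called lower adjusted over the list alone (camera adjusted p = 0.415). Their mean was -0.13 without cisplatin 3, 0.00 at position 2 and -0.56 to 0.35 on the 4 slides. On the same slides the alveolar type 2 mean was -0.36 to 0.22.

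Inhibitory immune receptors and ligands had a mean of 0.15 over 7 genes with 3 called adjusted over the list alone, all higher, and were not shifted by camera (adjusted p = 0.622). Fry's mixed test called that list (adjusted p = 0.00535), as it did Wnt targets (mean 0.08 over 13 genes) with the same adjusted p. TGF-beta targets were higher in 12 of 18 genes with a mean of 0.14 (camera adjusted p = 0.128), 0.08 without cisplatin 3 and -0.04 at position 2. The 4 measured metallothioneins, metal-binding proteins, were all higher, with a mean of 0.25, in a list too small to test. Hypoxia genes (-0.06 over 24), glycolytic enzymes (-0.01 over 17) and ribosomal protein genes (-0.02 over 46) were not called, with means of -0.11 to -0.01, -0.06 to 0.05 and -0.04 to 0.005 over the omissions of 1 array.

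The 4 measured sex-linked genes, too few for the list test, parted the arrays into 5 and 5 across the treatment. Their mean, about that of the 10 arrays, was 0.96 to 1.18 on 3 PBS and 2 cisplatin arrays and -1.22 to -0.77 on the other 2 PBS and 3 cisplatin arrays. The 3 PBS arrays, PBS 1, 2 and 3, were also the lowest arrays of the NF-kB list. The 2 cisplatin arrays, cisplatin 4 and 5, lay at 0.08 and 0.34 in that list, and the other 3 at 0.18 to 0.61. On slides 1, 2 and 4 the PBS and the cisplatin array lay on opposite sides of the sex-linked split. With that split as a fixed effect 85 genes were called, 62 of them among the 81, and 14 lists. Of the other splits of the arrays tested, this one called the most genes, 7. The genes that defined it stayed among the features tested, so some calls for it are given in advance. Which genes the 7 were is not given here.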
